A study of Mus musculus with 8 samples.

How the data were processed

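The series comprises 8 Hi-C libraries of mouse bone marrow cells, in 4 groups of 2. Hi-C joins DNA ends that lie close together in the nucleus and counts, by sequencing, how often each pair of genomic bins was joined. Per the labels' protocols, cells were sorted from mice 4 to 6 weeks old on a C57BL/6J background and processed with the Arima Hi-C kit and an NEBNext Ultra II library kit for sequencing on a NovaSeq. Granulocyte-monocyte progenitors (GMPs) were sorted at 200000 cells per library and neutrophils at 3000000, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.20 and HiC-Pro 3.1.0 were used and the genome build was mm10. HiC-Pro is a pipeline that maps Hi-C reads and bins contacts. The aligner, the filters on read pairs and the normalization of contacts are not given in the sources used here. Per the series' design text, each of the authors' processed files was made from replicates A and B together, so the replicates are not separate in such files.

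The file analysed here is 1 deposited index of genomic bins, with 4 columns, all of them used: chromosome, bin start, bin end and a running bin number. It holds 0 columns of contact values and belongs to no sample. Contact maps, read totals and loop, domain or compartment calls were not analysed here. The depth of the 8 libraries is therefore unknown here. No interval, mean, SD or p-value between groups is given, and no test of knockout against control was run. Replicate letters A and B occur in all groups, and no sources used here say whether they mark separate animals.

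The bins were checked for gaps, for width and for numbering. They were then joined to a table of 49997 RefSeq genes on assembly GRCm38.p6, the assembly that the name mm10 also stands for. All coordinates below are on this assembly and count from 1. A total of 49943 genes lie on chromosomes 1 to 19, X and Y, and 0 of them end beyond the last bin of their chromosome. The gene table gives gene spans without strand, exons or transcript starts. The plan, fixed before the data were examined, placed each gene by its 5′ end. Because strand was missing, each gene was placed instead by the middle of its span, which the plan had listed as an alternative, and the lower and higher ends of the span were added as alternatives after the file was seen. Counting the kit's cut sites per bin was also planned and was not run, because no genome sequence was used here.

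Also fixed before the data were examined were 6 gene lists with 173 entries (172 distinct genes): Toll-like receptor and NF-kB signalling, inflammatory cytokines and chemokines, neutrophil granule and effector genes, myeloid transcription factors, myeloid surface receptors, and markers of other blood cell types. All 172 symbols matched the gene table. Cxcl11 is annotated there as a transcribed pseudogene and was left out of the tests of protein-coding genes, which leaves 171 distinct genes and 172 entries (Pf4 is in 2 lists). For each list, the number of members whose middle lies in a bin with the middle of another member was compared with 10000 random lists of the same size drawn from 21887 protein-coding genes. The permutation test was one-sided, for an excess. The smallest p it can give is 0.0001, and p-values were adjusted by Benjamini-Hochberg over the 6 lists with a threshold of 0.05. The lists were written from textbook knowledge and contain gene families that are known to sit in clusters, so the test describes where these genes lie on the grid and carries no information about the cells. In a test on simulated data, lists of each size were drawn from the 21887 genes. All 200 lists with 3 planted pairs passed an unadjusted p threshold of 0.05 at every list size. Between 1 and 4 of 200 random lists did so. The planted outcome was fixed, because members of random lists share a bin so rarely that 3 pairs always pass. It gives no measure of how often lists with fewer pairs would pass.

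The text names genes by a rule fixed before the data were examined: Runx1 and Cebpa; in each list up to 6 sets of members that share a bin; and in each list the member that overlaps the most bins. One of the sets that the rule names is not reported here. Other genes named are said to be chosen after their values were seen. Alternatives were bins of 100 kb and 25 kb, boundaries moved by 25 kb, the ends of genes in place of their middles, all annotated genes, and random lists matched by chromosome or by gene density. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.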

Results

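Hi-C libraries were made from GMPs, the bone marrow progenitors of granulocytes and monocytes, and from bone marrow neutrophils. Mice carried floxed Runx1 alleles with a Cebpa-Cre transgene (knockout) or without it (control). Runx1 encodes a transcription factor of blood cell development. GMPs were sorted as lineage-negative, Kit-positive, Sca1-negative, CD16/32-positive and CD150-negative cells. Neutrophils were sorted as CD11b-positive and Ly6G-positive cells that lacked SiglecF and a macrophage surface marker. Each of the 4 groups had 2 libraries. GMP libraries were made from 200000 cells and neutrophil libraries from 3000000, so cell type and input differed together. The design implies a comparison of chromatin contacts between knockout and control in GMPs, the same comparison in neutrophils, and a comparison of the genotype effect between the cell types. None of these comparisons is reported, because contact values were not analysed here. The loss of Runx1 in the knockout libraries was not checked either. The results below describe the deposited grid of 50 kb bins, and the genes that this grid separates or merges. They apply equally to all 8 libraries, and they have no replicates. Because no contact map was analysed, it is unknown here whether contacts were also binned at other widths.

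The grid held 54521 bins on 22 sequences: chromosomes 1 to 19, X, Y and the mitochondrial genome. Of these bins, 54499 were 50 kb wide, and the last bin of each of the 22 sequences was shorter. The mitochondrial genome was a single bin of 16299 bp. The bins covered 2725537669 bp without gaps. Chromosome 1 had the most bins, 3910, and among the nuclear chromosomes chromosome 19 had the fewest, 1229. The grid allows 1486296981 distinct pairs of bins, counting each bin with itself. Of these, 75264131 pairs (5.06%) join bins of the same sequence.

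Runx1, the floxed gene, overlapped 5 bins and shared them with 0 other protein-coding genes. It spans 224609 bp of chromosome 16, from 92601466 to 92826074 (gene ID 12394). Its bins run from 92600001 to 92850000 and carry the numbers 20211 to 20215. The gene filled 97.1% of the first bin, all of bins 20212, 20213 and 20214, and 52.1% of the last. The only other annotated gene in these bins was Gm30281, which is not protein-coding and overlapped bin 20214. Contacts between parts of Runx1 in different bins would thus fall into separate cells of a map on this grid. Contacts between parts within the same bin would fall into a single cell. Cebpa, whose promoter names the Cre driver and which encodes a transcription factor of granulocyte development, lay within 1 bin. It spans 2636 bp of chromosome 7, from 35119293 to 35121928 (gene ID 12606), which is 5.27% of bin 41977 (35100001 to 35150000). That bin held 0 other protein-coding genes and 3 other annotated genes.

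**Figure D1:**
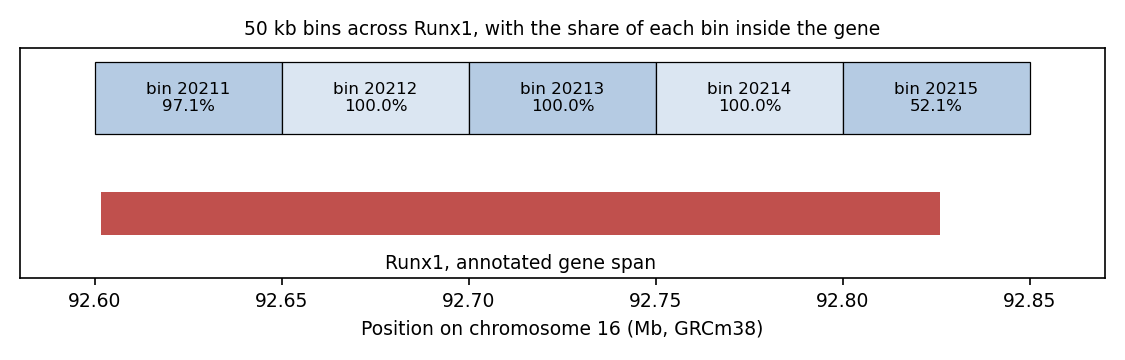
Map of Runx1 on chromosome 16 (horizontal axis, position in Mb, GRCm38). Blue boxes are the 5 bins of 50 kb with the percentage of each bin inside the gene, and the red bar is the annotated gene span. The gene fills all of 3 bins, 97.1% of the first and 52.1% of the last.

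Across the genome, 10261 of 21887 protein-coding genes (46.9%) had their middle in a bin that also held the middle of another protein-coding gene. Contacts of such a bin cannot be assigned to 1 of these genes from the bin alone. This count uses middles only. A gene that overlaps further bins may be told apart there, and genes with middles in different bins can still overlap in 1 bin. The share of genes whose middle shared a bin was highest on chromosome 7 (61.7% of 2030 genes) and chromosome 11 (61.2% of 1609 genes). It was lowest on Y (1.56% of 256 genes) and X (30.8% of 966 genes). The densest bin, on chromosome 18 from 37750001 to 37800000, held the middles of 17 genes, all of the gamma protocadherin cluster, from Pcdhga1 to Pcdhga11. In the other direction, 38873 of the 54520 bins on chromosomes 1 to 19, X and Y (71.3%) held the middle of no protein-coding gene. Genes that overlapped 2 or more bins numbered 9862 (45.1%). Dmd, which encodes dystrophin, overlapped the most bins, 49. Dmd and the protocadherins were named after their values were seen.

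Of the 29 protein-coding inflammatory cytokine and chemokine genes tested, 12 (41.4%) shared a bin with another member, against a mean of 0.0342 in random lists (adjusted p = 0.0001, one-sided permutation test). The lists contain gene families known to sit in clusters. A low p was therefore likely from the start, here and for the lists below that passed. Cxcl5, Ppbp, Pf4 and Cxcl3, which encode CXC chemokines, lay in 1 bin of chromosome 5 (90750001 to 90800000), within 28796 bp. Cxcl9 and Cxcl10, interferon-induced chemokines, shared the bin from 92300001 to 92350000 on the same chromosome. Ccl2 and Ccl7, chemokines that attract monocytes, shared a bin of chromosome 11 (82000001 to 82050000), as did Ccl9 and Ccl6 (83550001 to 83600000). Tnf and Lta, which encode tumour necrosis factor and lymphotoxin alpha, shared the bin of chromosome 17 from 35200001 to 35250000, with 1157 bp between them. Tnf crossed the lower boundary of that bin, with 634 bp below it and 2007 bp above it. Csf1, which encodes the macrophage growth factor M-CSF, was the longest of the members that overlapped 2 bins, the most in this list. Of the 29 genes, 12 were the only protein-coding gene with its middle in their bin. That count includes Ccl3 and Ccl4, named after their values were seen, whose spans overlap each other. Ccl4 had 1377 bp in the bin of Ccl3. With genes placed by their lower ends, 14 members shared a bin, Ccl3 and Ccl4 among them. By their higher ends, 12 did.

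**Figure D2:**
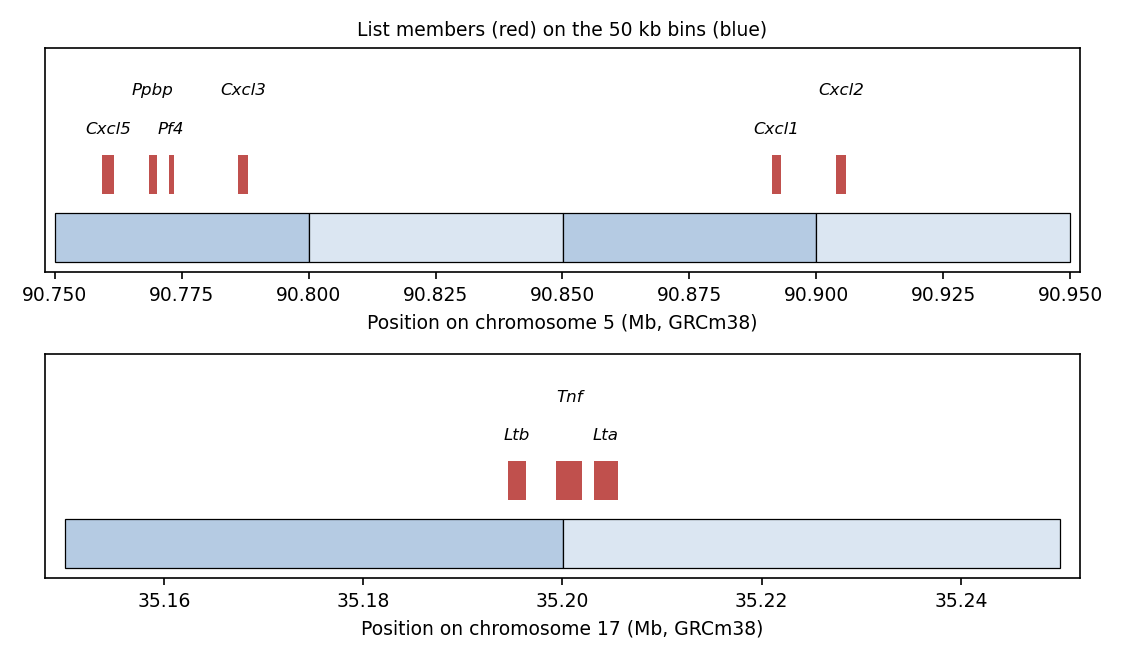
Positions of list members (red, to scale) above the 50 kb bins (alternating blues) on chromosome 5 (upper panel) and chromosome 17 (lower panel), with position in Mb on the horizontal axes. Cxcl5, Ppbp, Pf4 and Cxcl3 lie in 1 bin. Cxcl1 and Cxcl2 lie in other bins, which neighbour each other but not that bin. A boundary passes through Tnf and separates Ltb from Lta.

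None of the 42 Toll-like receptor and NF-kB signalling genes shared a bin with another member, a count of 0 against a mean of 0.0694 in random lists (adjusted p = 1.0, one-sided permutation test). This count depended on where the boundaries lie. With boundaries moved by 25 kb, 2 members, Tlr1 and Tlr6, shared a bin (adjusted p = 0.0323, one-sided permutation test). That p rests on a single pair, the smallest count above 0, and passes because random lists had a mean of only 0.065. The p of the main count follows from the count of 0. Neither value measures an excess across the pathway. Tlr1 and Tlr6, receptors for bacterial lipopeptides that were named after their values were seen, lie in neighbouring bins of chromosome 5. Of the 42 genes, 24 were the only protein-coding gene with its middle in their bin. Nfkb1, which encodes the p105 and p50 NF-kB proteins, spans 107315 bp of chromosome 3 (135584655 to 135691969) and was the longest of the members that overlapped 3 bins, the most in this list.

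Among the 25 neutrophil granule and effector genes, 6 (24.0%) shared a bin with another member, against a mean of 0.0252 in random lists (adjusted p = 0.0001, one-sided permutation test). S100a8 and S100a9, the subunits of calprotectin, shared a bin of chromosome 3 (90650001 to 90700000). Prtn3 and Elane, serine proteases of azurophil granules, shared a bin of chromosome 10 (79850001 to 79900000) that held the middles of 5 protein-coding genes. Lyz2 and Lyz1, the lysozymes, shared another bin of that chromosome (117250001 to 117300000). Itgam, which encodes the CD11b antigen used in the neutrophil sort, overlapped 2 bins of chromosome 7, from 128062640 to 128118491.

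Of the 27 myeloid transcription factor genes, 3 (11.1%) shared a bin, against a mean of 0.0308 in random lists (adjusted p = 0.0001, one-sided permutation test). These were Hoxa7, Hoxa9 and Hoxa10, homeobox genes of progenitor cells, in the bin of chromosome 6 from 52200001 to 52250000. Runx2, a paralog of Runx1 known for its role in bone, overlapped the most bins of this list, 8, over 318811 bp of chromosome 17. Of the list, 18 genes, Runx1 and Cebpa among them, had a bin with no other protein-coding middle.

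Of the 22 myeloid surface receptor genes, 6 (27.3%) shared a bin, against a mean of 0.0164 in random lists (adjusted p = 0.0001, one-sided permutation test). Cxcr2 and Cxcr1, chemokine receptors of neutrophils, shared a bin of chromosome 1 (74150001 to 74200000). The formyl peptide receptor genes Fpr1 and Fpr2 shared a bin of chromosome 17 (17850001 to 17900000). Il1r1, the interleukin 1 receptor gene, overlapped 3 bins of chromosome 1. Of the 27 markers of other blood cell types, 9 (33.3%) shared a bin, against a mean of 0.027 in random lists (adjusted p = 0.0001, one-sided permutation test). They were the complement genes C1qb, C1qc and C1qa on chromosome 4, the globin pairs Hbb-bt with Hbb-bs on chromosome 7 and Hba-a1 with Hba-a2 on chromosome 11, and the T cell receptor subunit genes Cd3g and Cd3d on chromosome 9. Ebf1, a B cell transcription factor gene, overlapped 9 bins of chromosome 11.

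**Figure D3:**
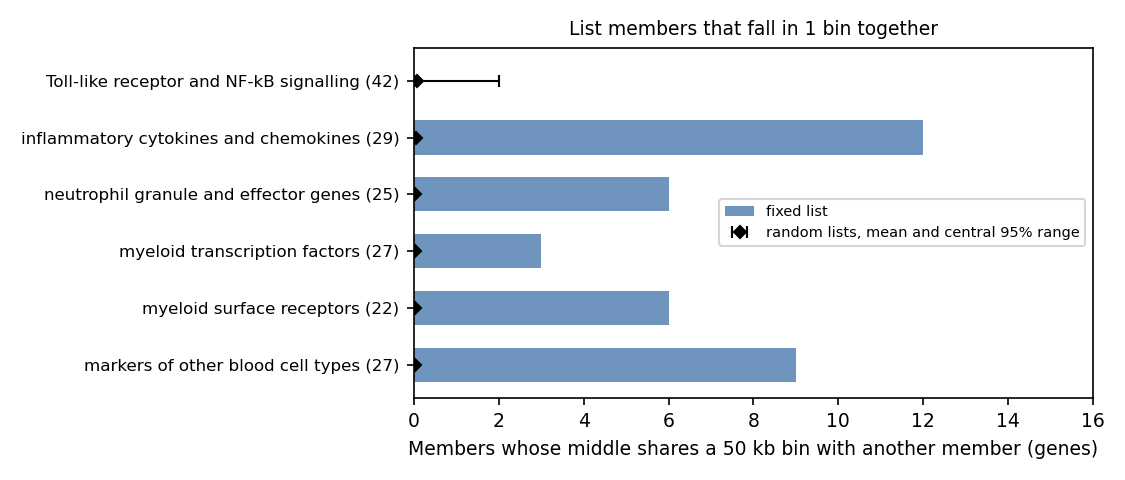
Number of list members that share a 50 kb bin with another member of their list (horizontal axis, genes) for the 6 lists, with the number of members in parentheses. Bars are the fixed lists, and diamonds with whiskers are the mean and the central 95% range of 10000 random lists. The cytokine and chemokine list reaches 12 genes and the Toll-like receptor list 0.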

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

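Of 42 repeats of the 6 list results, 40 kept their direction and their side of the threshold of 0.05. The other 2 were in the Toll-like receptor and NF-kB list, where the count rose from 0 to 2 with 100 kb bins (adjusted p = 0.0729) and to 2 with boundaries moved by 25 kb (adjusted p = 0.0323, permutation tests). In both, the 2 genes were Tlr1 and Tlr6, and over all 7 repeats of this list the adjusted p ranged from 0.0323 to 1.0. The matched random lists leave the counts unchanged by construction. With boundaries moved by 25 kb, Cxcl9 with Cxcl10, S100a8 with S100a9, Cxcr2 with Cxcr1 and Hbb-bt with Hbb-bs no longer shared a bin. Cxcl3 and Hoxa7 left their sets. Counts fell from 6 to 4 for neutrophil genes and for surface receptors, and from 3 to 2 for transcription factors. They fell from 9 to 8 for other blood cell markers and rose from 12 to 14 for cytokines and chemokines. The number of protein-coding genes that share a bin, 10261 (46.9%), was 5334 (24.4%) with 25 kb bins, which are narrower by construction. It rose to 33721 (67.5% of 49943) when all annotated genes were counted, which adds genes by construction. It was 15223 with 100 kb bins, and changed less with moved boundaries (10278) and at the lower (11295) or higher (11249) ends of genes. Placing genes by their 5′ ends and counting cut sites could not be done, for want of strand and sequence. Of the alternatives given here, the gene ends and the density-matched lists were chosen after the file was seen. No paired analysis was possible because no value per sample was analysed. For the same reason, no library could be left out, and nothing here depends on sequencing depth.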

Other observations

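Of the 171 distinct list genes, 111 lay within 1 bin, 44 crossed 1 boundary and 16 overlapped 3 or more bins. The boundaries cut several genes very unevenly. Ctsg, which encodes cathepsin G of azurophil granules, had 116 bp below a boundary of chromosome 14 and 2574 bp above it. Il1a had 392 bp below a boundary of chromosome 2 and 10186 bp above it, and Ms4a1, which encodes the B cell antigen CD20, had 322 bp and 16149 bp on chromosome 19. Irf3 was cut near its middle, with 2353 bp and 2848 bp. Leaving aside Pf4, which is in 2 lists, genes of different lists came together in 1 bin, on chromosome 15 from 78250001 to 78300000: Ncf4, a subunit gene of the neutrophil NADPH oxidase, and Csf2rb2, a cytokine receptor gene. These genes were chosen after their values were seen.

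The clustering of cytokine and chemokine genes on the grid was weighed against other explanations; the test with 1 member per protein family was chosen after the result was seen. Random lists matched on the number of protein-coding genes per bin shared a bin in a mean of 0.21 members against 12 observed. The permutation p was 0.0001, the smallest that 10000 lists can give. Genes drawn independently from bins of like gene number thus rarely shared a bin. A low p was therefore close to fixed, and the matching counted the list members themselves, so this test cannot decide on general gene density. With boundaries moved by 25 kb, 14 members shared a bin (permutation p = 0.0001), so the excess also held at this other placement. However, the sets of sharing members spanned 6212 to 28796 bp, less than the width of a bin. Many could thus stay together after a move, and a few pairs suffice for a low p. The test therefore decides little about the boundaries as a source of the excess. Which members shared did depend on the boundaries. Cxcl9, Cxcl10 and Cxcl3 no longer did, while Cxcl1, Cxcl2, Ccl3, Ccl4 and Ltb, named after their values were seen, did. Keeping 1 member per symbol stem left 4 sharing members of 9, Pf4 with Ppbp and Tnf with Lta (permutation p = 0.0001). However, the genes of each pair belong to the same protein family under different symbols, so that test decides nothing. Keeping 1 member per protein family left 0 sharing members of 11 (permutation p = 1.0), but every set of sharing members lay within 1 family, so this outcome was fixed and that test decides nothing either. All 12 sharing members thus shared their bin with a member of their own family. Neither family test can say whether the families account for the clustering beyond that.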
